A study of Homo sapiens with 8 samples.

How the data were processed

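Poly(A) RNA of HepG2 cells was sequenced from 8 libraries, 2 in each of 4 groups, as single-end reads of 50 bases. The groups crossed a miR-552-3p mimic or control mimic (1 nM) with an importin8 siRNA or control siRNA (30 nM), for 72 h. Each library was put in its group by its sample title. The columns of the tables carry abbreviated names, and were matched to the titles by reading those abbreviations: the column names with 51 or 52 after NC or SI were read as the mimic libraries of the control and the importin8 siRNA arm. No column of per-sample values was left unread. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The replicates of each group differed by more than sampling noise (chi-square per degree of freedom 10.6, 7.74, 5.31 and 4.52 in NC, miR-552-3p, siIPO8-NC and siIPO8-miR-552-3p), so each counted as a sample of its own.

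Per the file headers, the deposited tables give for each gene and library an expected count and an FPKM. Names and versions in the submitters' processing notes are HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.8 and the genome GRCh38.p12, with no role stated there. The values of expected count behave as counts shared out among genes: 24.3 to 26.5% of them were whole numbers within a tolerance of 1e-06, and they summed to 21608563 to 22102373 per library. FPKM was used only as a check of the unit, where the gene length it implied had a median of 2611 to 2783 bases over genes with an FPKM of at least 5. A table of the 4 control siRNA libraries with 25738 genes repeats values of the table of all 8 with 0 differing cells. It lacks 978 genes of the table of 8, so all work used the table of 8. That table holds 21842 genes listed as mRNA, 4347 as lncRNA, 524 as pseudogenes and 3 of other kinds. Of its gene identifiers 22421 (83.9%) were found in the reference gene table, 3656 are predicted genes with no name and 26 symbols read as dates. The gene with the most counts in each library is such an unnamed prediction, and took 11.27 and 11.6% of the counts in NC and 6.9 to 8.92% elsewhere. Expected counts divide reads among genes that share sequence, so levels of close paralogs, pseudogenes and overlapping or antisense genes are uncertain, and whether strand was used is not given in the sources used here.

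Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr on the groups, which kept 17715, library sizes were scaled by TMM (factors 0.961 to 1.06), and all 8 libraries were fitted together with a mean per group in edgeR 4.0.16 (quasi-likelihood F test, robust). A gene was called with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The SE given is the absolute log2 fold change over the square root of the F statistic, and is approximate. The contrasts were the mimic with control siRNA, the mimic with importin8 siRNA, the importin8 siRNA with control mimic, and the difference between both mimic effects. The siRNA effect among the mimic libraries was added after the NC libraries were seen at one end of the first principal component. CPM are scaled by the TMM library sizes. A group with no counts was set at 3 counts per library, 0.133 to 0.143 CPM, for a lower bound of the fold. Such bounds and intervals cover counting error only. Gene positions are those of the GRCh38 annotation used as reference.

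The study labels, groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule named IPO8 first, then per comparison the 12 genes with the largest rise and the 12 with the largest fall in log2 fold change among called genes with a usual symbol, a mean of at least 100 counts over the libraries compared and both libraries of one group above both of the other, and 6 in each direction for the difference. It added 14 genes of the study's theme (NR1H4, NR1H3, NR1H2, NR0B2, CYP7A1, SREBF1, FASN, SCD, ACACA, G6PC, PCK1, FBP1, ABCA1 and CYP2E1) and up to 4 called members of each list. The text leaves out some members whose call depended on single libraries. MYLK4 in the siRNA comparison is one of these: its value was -5.49 (adjusted p = 0.012), and without NC replicate 2 it was -5.52 (adjusted p = 0.052). A few other members are not reported here.

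The 24 gene lists cover FXR and LXR targets, gluconeogenesis, glycolysis, glycogen, fatty acid and triglyceride synthesis, cholesterol, fatty acid oxidation, lipoproteins, bile acids, drug metabolism, hepatocyte genes, cell cycle, p53 targets, interferon, acute phase, stress responses, importins and exportins, the microRNA pathway, ribosomal proteins, oxidative phosphorylation, and markers of fibroblasts, of endothelial and blood cells and of cholangiocytes and progenitors. Of their 482 distinct members 478 are in the table. Each list was tested against all other genes with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 96 planned list tests. The added comparison was adjusted over its 24 lists. With the correlation estimated from the data no list passed in any comparison. The power of that version with 2 libraries per group was not tested. The median, mean and test of a list differed in sign where the text says so and, among lists that did not pass, for importins and markers of fibroblasts and of endothelial and blood cells with the mimic and importin8 siRNA, for drug metabolism and the same markers with the siRNA and control mimic, and for endothelial and blood cell markers in the difference. No list that passed changed the sign of its median under median-ratio, upper-quartile or library-size scaling.

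Words in 3' UTRs came from the longest coding transcript of each gene with a UTR of at least 50 bases, found for 13544 of 17715 tested genes (96.5% of the 14012 coding genes with a name), with a median length of 1272 bases. For each heptamer, the mean log2 fold change of genes with and without the word was compared after log UTR length was taken out, and its standing among all heptamers gave the test, in which the lowest or highest 2.5% passed. Versions with GC content also taken out, and without UTRs that hold an Alu-like stretch, were chosen after the data were seen.

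The fit was tested on simulated negative binomial counts with the fitted spread and no difference between groups other than 200 planted changes. Of 67 genes planted at 1.5-fold, 67 at 2-fold and 66 at 4-fold among 17715, the mimic comparison with control siRNA recovered 44.8, 61.2 and 72.7% with 16 false calls, and that with importin8 siRNA 34.3, 62.7 and 80.3% with 14. The siRNA comparison with control mimic recovered 49.3, 62.7 and 66.7% with 13 false calls, that with the mimic 47.8, 64.2 and 75.8% with 10, and the difference between mimic effects 20.9, 56.7 and 74.2% with 17. In the word test a shift of -0.2, planted in shuffled fold changes of the mimic with control siRNA, ranked first in 2 of 5 trials and 24th at worst. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and count filters, fits of the 4 libraries compared, the replicate number as a block, a fold minimum, other list tests and words, and each library left out in turn. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.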

Results

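The series asked how a synthetic miR-552-3p mimic changes the transcripts of HepG2 cells, a human hepatocellular carcinoma line, and whether lowering importin8 (gene IPO8) alters that response. Its title places the question in the activity of the nuclear receptors FXR and LXR and in hepatic sugar and lipid metabolism. The 4 groups of 2 libraries each crossed a mimic or a control mimic at 1 nM with an siRNA to importin8 or a control siRNA at 30 nM for 72 h. They are called NC (both controls), miR-552-3p (mimic with control siRNA), siIPO8-NC (importin8 siRNA with control mimic) and siIPO8-miR-552-3p (both active). The expected counts of a library summed to 22102373 and 21608563 in NC, 22060634 and 21665807 in miR-552-3p, 22061806 and 21764984 in siIPO8-NC and 21660769 and 21641985 in siIPO8-miR-552-3p. Of 26716 genes in the table, 17715 had enough counts to be tested. Levels are given in CPM, counts scaled to library size, as mean ± SD with n = 2 libraries per group.

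IPO8, which encodes a nuclear import receptor and lies on chromosome 12 from 30628988 to 30695986 on the minus strand, was at 34.0 ± 0.952 CPM in NC, 25 ± 0.541 in miR-552-3p, 11.4 ± 0.0835 in siIPO8-NC and 7.97 ± 0.465 in siIPO8-miR-552-3p. It was thus at 33.6% of its NC level with the importin8 siRNA alone, at 23.5% with siRNA and mimic together, and at 73.6% with the mimic alone. The siRNA effect was -1.57 on the log2 scale with the control mimic (SE 0.08; adjusted p = 4.5e-07). IPO8 also fell with the mimic, by 0.44 with control siRNA (SE 0.08; adjusted p = 0.00083) and by 0.52 with importin8 siRNA (SE 0.09; adjusted p = 0.0022), edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The difference between these mimic effects was -0.07 (SE 0.12; adjusted p = 0.70).

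**Figure D1:**
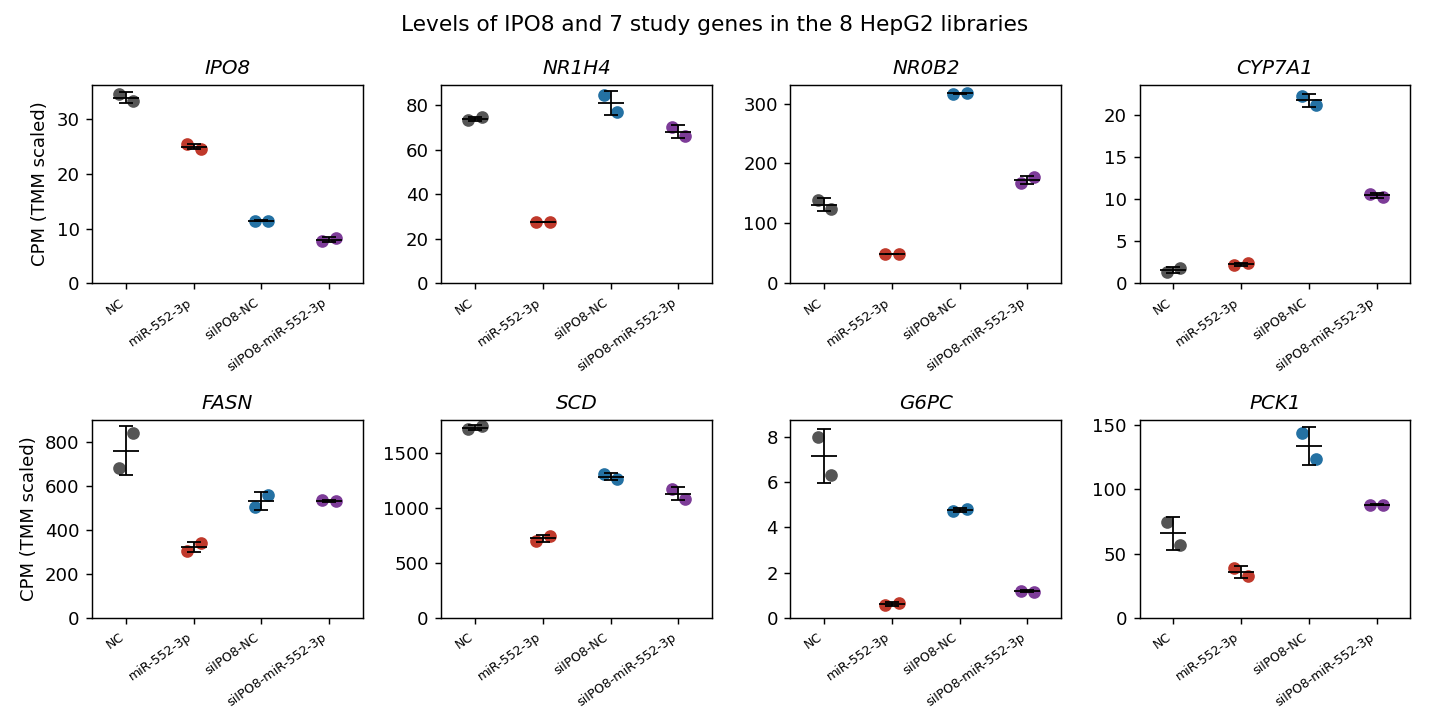
Levels of IPO8, NR1H4, NR0B2, CYP7A1, FASN, SCD, G6PC and PCK1 in CPM (linear axis from 0) in the 4 groups; points are libraries, bars the mean ± SD of 2 libraries. NR0B2 stood at 131, 49.2, 317 and 172 CPM and CYP7A1 at 1.55, 2.23, 21.8 and 10.4 CPM in NC, miR-552-3p, siIPO8-NC and siIPO8-miR-552-3p.

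The first question was what the mimic changes when importin8 is not lowered by siRNA. Against NC, the mimic lowered NR1H4, which encodes FXR, from 74.0 ± 1.03 to 27.5 ± 0.0636 CPM and NR0B2, which encodes the FXR-induced repressor SHP, from 131 ± 10.6 to 49.2 ± 0.149 CPM. Most measured genes of cholesterol and fatty acid synthesis, lipoproteins and the cell cycle fell, while most genes of the integrated stress response, p53 targets and ribosomal proteins rose. These lists passed with the preset correlation, and each call was lost with an estimated correlation, at adjusted p = 0.24 to 0.69. The largest falls reached genes that NC expressed well: SLC6A12, a transporter of betaine, went from 423 ± 4.67 to 0.464 CPM, and PGC, the precursor of a digestive protease, from 2287 ± 32.7 to 26.3 ± 0.384 CPM. The NC libraries lay at one end of the first principal component, which held 51.4% of the variance, at -88.8 and -94.3, with siIPO8-NC at -19.3 and -24.7, siIPO8-miR-552-3p at 41.1 and 38.3 and miR-552-3p at 75.3 and 72.4. On the second, with 23.5%, NC lay at 36.9 and 38.7, beside miR-552-3p at 44.8 and 45.1 and away from siIPO8-NC at -56.3 and -54.8. NC differed from siIPO8-NC by 0.906 in log2 (root mean square over genes), less than miR-552-3p did at 1.04, and from miR-552-3p by 1.26. From siIPO8-miR-552-3p, miR-552-3p differed by 0.705 and siIPO8-NC by 0.669.

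Among the genes chosen for the study's theme, NR1H4 (chromosome 12, 100473708 to 100564413) fell by 1.43 (SE 0.07; adjusted p = 8.2e-08) and NR0B2 (chromosome 1, 26911489 to 26913966) by 1.41 (adjusted p = 1.1e-07). The lipogenic enzymes FASN, SCD and ACACA fell by 1.24, 1.26 and 1.22, FASN from 762 ± 112 to 323 ± 23.2 CPM and SCD from 1728 ± 20.9 to 723 ± 31.3 CPM. G6PC, the last enzyme of glucose release, fell by 3.55 from a low 7.16 ± 1.2 CPM (adjusted p = 8.4e-07), and PCK1, the enzyme that makes phosphoenolpyruvate for gluconeogenesis, by 0.88 (adjusted p = 0.0016). ABCA1, a cholesterol exporter and LXR target, rose by 0.63 (adjusted p = 0.00015). The LXR genes NR1H3 and NR1H2 had values of -0.06 and 0.05, and SREBF1, an LXR target that drives lipogenesis, -0.14, none of which passed. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was near the limit of measurement at 1.55 ± 0.348 and 2.23 ± 0.177 CPM. Its value of 0.52 passed (adjusted p = 0.037), but 7 of 8 fits that each left out 1 library lost that call, all but the fit without NC replicate 2, at 0.31 to 0.60 and adjusted p = 0.054 to 0.33. DESeq2, limma-voom and a fit of the 4 libraries compared lost it too. CYP2E1 and FBP1 had too few counts to be tested, at most 17 and 5 in any library.

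Of the genes that rose most, TM4SF19 and TAGLN3 had no counts in NC and were at least 159-fold and 114-fold higher at 21.2 ± 2.95 and 15.2 ± 0.145 CPM, taking 3 counts per library as the floor. ATP6V0D2, a vacuolar proton pump subunit, had 0 and 1 counts in NC and 26.2 ± 4.72 CPM with the mimic; KLHDC7B had 0 and 3 counts and 13.7 ± 0.410 CPM, and CA12, a carbonic anhydrase, 3 and 1 counts and 17 ± 1.2 CPM. IGFN1 rose by 9.20, KRT20 (an intestinal keratin) by 9.04, HSPA6 (an inducible heat shock protein) by 8.36, ESAM by 8.19, C5AR1 (a complement receptor) by 8.01, MYOF by 7.70 and TAGLN (an actin-binding protein of smooth muscle) by 7.65. Among those that fell most, AQP6, GLP2R and SLC7A10 went from 25.4 ± 2.32, 29.9 ± 1.35 and 13.6 ± 0.664 CPM to 0 and 2, 2 and 1, and 0 and 3 counts. PTGS1, the constitutive cyclooxygenase, changed by -7.77, CDH16, a cadherin, by -7.42, SOWAHA by -7.05, ANXA13 by -6.68, PGC by -6.44, FAM167B by -6.32, MYLK4 by -6.01 and ETNPPL, a phosphoethanolamine lyase, by -5.90.

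In lipid metabolism, of 25 measured genes of cholesterol synthesis and uptake 22 fell, 1 rose and 2 did not pass, with the same numbers adjusted over the list alone. LSS, MVK and DHCR7, enzymes of the sterol pathway, fell by 2.48, 2.27 and 2.23. The list median was -1.53 (adjusted p = 3.7e-10, and adjusted p = 0.24 with an estimated correlation). Of 17 genes of fatty acid and triglyceride synthesis 12 fell, 13 adjusted over the list alone, and none rose, among them PNPLA3 at -3.04, DGAT1, which makes triglycerides, at -2.01 and FADS2 at -1.54. The median was -1.02 (adjusted p = 7.0e-05, and adjusted p = 0.47 with an estimated correlation). Of 18 apolipoprotein and lipoprotein assembly genes 14 fell and 2 rose, also adjusted over the list alone, with APOA5 at -4.26, APOA4 at -2.89 and MTTP, which loads lipid onto apolipoprotein B, at -2.43. The median was -0.79 (adjusted p = 0.00075, and adjusted p = 0.57 with an estimated correlation). Of 21 genes of fatty acid oxidation and ketogenesis 11 fell and 3 rose, also adjusted over the list alone, with BDH1 at -2.98, SLC25A20 at -2.54 and EHHADH at -1.99. The median was -0.48 (adjusted p = 0.040, and adjusted p = 0.57 with an estimated correlation). The call of that list was lost without NC replicate 1 or miR-552-3p replicate 2, at adjusted p = 0.067 to 0.13.

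FXR targets as a list did not pass: of 20 measured, 10 fell and 5 rose, also adjusted over the list alone (median -0.38; adjusted p = 0.24). CYP8B1, a bile acid hydroxylase that FXR activity lowers, fell by 4.16, and APOC3 and UGT2B4 fell by 2.35 and 1.79, while the fibrinogen chain FGB rose by 3.25. Of 18 LXR targets 7 fell and 4 rose, also adjusted over the list alone (median -0.08; adjusted p = 0.54), with MLXIPL at -2.37 and SMPDL3A at 2.27. Of 17 genes of bile acid synthesis and transport 8 rose and 6 fell (median 0.20; adjusted p = 0.58), with AKR1C4 at 2.91 and ABCC4 at 2.16. In sugar metabolism, 5 of 10 gluconeogenesis genes rose and 5 fell (median -0.22; adjusted p = 0.79), with CREB3L3 at -3.89, GOT1 at 1.88 and TAT at 1.32. Of 20 glycolysis genes 11 rose and 4 fell (median 0.43; adjusted p = 0.14), with the kinases PFKP and HK2 at 3.58 and 2.67 and the liver pyruvate kinase PKLR at -2.31. Of 12 glycogen genes 6 rose and 3 fell (median 0.34; adjusted p = 0.37), with PPP1R3B at 3.95 and PPP1R3C at -2.31.

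Proliferation and stress genes moved in opposite directions. Of 28 cell cycle genes 21 fell and none rose, also adjusted over the list alone, including E2F1 from 40.6 ± 0.794 to 7.77 ± 0.400 CPM, the helicase subunit MCM3 at -1.81 and TOP2A at -1.69. The median was -0.58 (adjusted p = 4.4e-05, and adjusted p = 0.47 with an estimated correlation). Of 21 genes of the integrated stress and unfolded protein responses 19 rose and 2 fell, also adjusted over the list alone, with CHAC1 at 3.80, ATF3 at 2.68, DDIT3 (the transcription factor CHOP) at 2.63 and asparagine synthetase ASNS from 36.2 ± 3.10 to 211 ± 9.11 CPM. The median was 1.31 (adjusted p = 1.8e-07, and adjusted p = 0.52 with an estimated correlation). Of 20 p53 targets 12 rose and 4 fell, 12 and 5 adjusted over the list alone, with PMAIP1 at 3.12, SESN2 at 2.42, GADD45A at 2.27 and GDF15 at 2.12. The median was 0.74 (adjusted p = 0.0049, and adjusted p = 0.55 with an estimated correlation). SESN2 is a member of the stress list as well, and GDF15, PMAIP1 and GADD45A are also known to respond to the stress factors ATF4 and CHOP. Of 26 cytosolic ribosomal protein genes 21 rose and none fell, 23 adjusted over the list alone, RPS18 at 0.96 and RPL8 at 0.76 (median 0.49; adjusted p = 5.2e-05, and adjusted p = 0.69 with an estimated correlation).

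Of 30 genes of hepatocyte secretion and lineage 19 fell and 6 rose, also adjusted over the list alone, with hemopexin HPX at -3.64, the nuclear receptor NR5A2 at -3.14 and the fibrinogen chain FGA rising from 75.8 ± 15.7 to 474 ± 15.6 CPM. The median was -0.51 (adjusted p = 0.010, and adjusted p = 0.67 with an estimated correlation). Of 18 drug metabolism genes 10 fell and 5 rose (median -0.62; adjusted p = 0.24), among them CYP3A7 at -5.02, CYP3A5 at -3.56 and CYP1A1 at -3.30. Of 21 interferon response genes 9 fell and 1 rose (median -0.11; adjusted p = 0.30), IFI6 at -3.22 and ISG20 at 2.21. Of 19 acute phase and NF-kB genes 8 fell and 7 rose (median -0.20; adjusted p = 0.71), the chemokine CXCL8 at 5.08 and the iron hormone HAMP at 2.79. Of 21 importins and exportins 11 rose and 4 fell (median 0.25; adjusted p = 0.054), KPNA4 at 1.04 and XPOT at 0.96. Of 18 microRNA pathway genes 6 fell and 4 rose (median -0.11; adjusted p = 0.71), AGO2 at 1.19 and DICER1 at -0.71. Of 24 oxidative phosphorylation genes 11 rose and 3 fell (median 0.19; adjusted p = 0.27), SDHB at 0.61 and COX4I1 at -0.83. Adjusted over the list alone, every list of this comparison for which it is not stated gave the same numbers. Markers of other cell types moved both ways. Of 11 fibroblast markers 5 rose and 2 fell (median 0.06, mean 1.26; adjusted p = 0.53), TAGLN and COL1A1 at 7.65 and 3.43 and SPARC at -4.25. Of 10 endothelial and blood cell markers 3 rose and 4 fell (adjusted p = 0.58), CD79A at 5.44, CD68 at 4.13 and VWF at -2.19. The median of that list was -0.49 and its test pointed down while its mean was 0.55. Of 10 cholangiocyte and progenitor markers 4 rose and 2 fell (median 0.23; adjusted p = 0.31), KRT19 rising from 31.3 ± 5.64 to 662 ± 20.5 CPM and SOX4 from 7.71 ± 0.553 to 163 ± 9.98 CPM.

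In all, 10341 of 17715 genes changed (58.4%), 5120 higher and 5221 lower, and 4432 of them at least 2-fold, 1992 higher and 2440 lower. With each library left out in turn the number of called genes lay between 8887 and 10180. Over other tools, scalings, filters and left-out libraries 45.4 to 50.8% of the called genes were higher, so neither direction held a majority throughout.

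The second question was what the mimic changes when importin8 is lowered, a comparison whose fold changes contrast no NC library. Its spread, scaling and gene filter came from all 8 libraries, NC included. Most stress genes and p53 targets rose and most cell cycle and cholesterol genes fell with siIPO8-miR-552-3p against siIPO8-NC, as did 8 of 17 genes of fatty acid and triglyceride synthesis and 8 of 18 lipoprotein genes. These lists passed, and so did the FXR target list, which fell. That list mixes genes that FXR activity raises and genes that it lowers. Each of these calls was lost with an estimated correlation, at adjusted p = 0.30 to 0.55. NR0B2 fell from 317 ± 0.842 to 172 ± 6.75 CPM. FASN was at 533 ± 39.6 and 534 ± 4.16 CPM. CYP7A1 fell from 21.8 ± 0.756 to 10.4 ± 0.267 CPM.

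Of the study's theme, NR0B2 fell by 0.88 (adjusted p = 1.6e-05), CYP7A1 (chromosome 8, 58490178 to 58500236) by 1.06 (SE 0.13; adjusted p = 0.00023) and G6PC by 2.02 (SE 0.23; adjusted p = 0.00014). FASN had a value of 0.00 (SE 0.10; adjusted p = 0.99) and SCD of -0.19 (adjusted p = 0.093), and neither passed. SCD passed in fits without either NC library, at adjusted p = 0.039 and 0.041. NR1H4 fell by 0.25 (adjusted p = 0.018), a call lost with DESeq2 and without siIPO8-NC replicate 1 or either siIPO8-miR-552-3p library, at -0.28 to -0.18 and adjusted p = 0.052 to 0.16. PCK1 fell by 0.60 (adjusted p = 0.016), lost in fits without the same 3 libraries at adjusted p = 0.068 to 0.078. ABCA1 fell by 0.33 (adjusted p = 0.016), lost without siIPO8-NC replicate 2 or siIPO8-miR-552-3p replicate 2 at adjusted p = 0.11 to 0.17, and ACACA by 0.35 (adjusted p = 0.0047), lost without siIPO8-miR-552-3p replicate 2 at adjusted p = 0.057.

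C5AR1 rose from 1.93 ± 0.257 to 31.3 ± 1.43 CPM and AKAP12, a scaffold of protein kinase A, from 86.4 ± 9.06 to 766 ± 69.0 CPM. Other genes that rose most were OSCAR at 3.87, the receptor GPRC5A at 3.15, SERPINB8 at 2.96, the EGF receptor ligand AREG at 2.92, the actin-bundling PALLD at 2.79, SLC43A3 at 2.75, the small heat shock protein CRYAB at 2.74, SH2D5 at 2.64, the matrix protease MMP3 at 2.62 and the water channel AQP3 at 2.60. The steepest falls were those of LGALS2 at -3.12, TBX10 at -2.68, PBLD at -2.66, NPTXR at -2.24, APOA4 at -2.16, CDH16 at -2.12, PAGR1 at -2.08, RBP5 at -2.07, REEP6 at -2.02, ABHD15 at -1.95 and PGC at -1.94. APOA5, an apolipoprotein that lowers plasma triglycerides, fell from 56.6 ± 0.353 to 13.5 ± 0.987 CPM.

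Of the 20 FXR targets measured 9 fell and 3 rose, 10 and 3 adjusted over the list alone. The median was -0.55 (adjusted p = 0.0067, and adjusted p = 0.52 with an estimated correlation). CYP8B1 fell by 2.94 and APOC3 by 1.17, while BAAT, which joins bile acids to glycine or taurine, rose by 1.18 and FGB by 1.08. Since CYP8B1 and CYP7A1, which FXR activity lowers, are among the members that fell, the list does not give a direction of FXR activity. The difference between the mimic effects on this list did not pass (median -0.18 with a test that pointed up; adjusted p = 0.97). Of 25 cholesterol genes 14 fell and 1 rose, also adjusted over the list alone, DHCR7 at -1.05 and MSMO1 at -0.99. The median was -0.33 (adjusted p = 5.2e-05, and adjusted p = 0.30 with an estimated correlation). Of 18 lipoprotein genes 8 fell and 1 rose, also adjusted over the list alone, LCAT at -1.66. The median was -0.19 (adjusted p = 0.00015, and adjusted p = 0.55 with an estimated correlation). Of 17 genes of fatty acid and triglyceride synthesis 8 fell and 2 rose, also adjusted over the list alone, PNPLA3 at -1.41, DGAT1 at -1.23 and DGAT2 at -0.95. The median was -0.22 (adjusted p = 0.0031, and adjusted p = 0.55 with an estimated correlation). Of 21 fatty acid oxidation genes 10 fell and 2 rose, 11 and 3 adjusted over the list alone, EHHADH at -1.33 and SLC25A20 at -0.91 (median -0.38; adjusted p = 0.0071, and adjusted p = 0.55 with an estimated correlation).

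Of 28 cell cycle genes 23 fell and none rose, 24 adjusted over the list alone, with E2F1 at -1.23, CCNE1 at -1.05, MCM3 at -0.99 and TOP2A at -0.89. The median was -0.54 (adjusted p = 2.8e-12, and adjusted p = 0.30 with an estimated correlation). Of 21 stress response genes 17 rose and 1 fell, also adjusted over the list alone, DNAJB9 at 1.55, ASNS at 1.43, the chaperone HSPA5 at 1.35 and SDF2L1 at 1.34. The median was 0.75 (adjusted p = 9.6e-10, and adjusted p = 0.47 with an estimated correlation). Of 20 p53 targets 13 rose and 2 fell, also adjusted over the list alone, PMAIP1 at 1.2, FAS at 0.95 and GDF15 at 0.74. The median was 0.46 (adjusted p = 6.3e-05, and adjusted p = 0.47 with an estimated correlation). Of 30 hepatocyte genes 12 fell and 2 rose, also adjusted over the list alone, TTR at -1.21 and VTN at -0.77 (median -0.15; adjusted p = 0.017, and adjusted p = 0.68 with an estimated correlation), and the call was lost without siIPO8-NC replicate 1 at adjusted p = 0.077. Of 26 ribosomal protein genes 3 rose and none fell, 1 adjusted over the list alone (median 0.15; adjusted p = 0.034, and adjusted p = 0.79 with an estimated correlation), a call lost without siIPO8-NC replicate 2 or siIPO8-miR-552-3p replicate 2 at adjusted p = 0.087 to 0.13. LXR targets, with 6 of 18 lower and 1 higher (adjusted p = 0.12), gluconeogenesis, with 6 of 10 lower and 4 higher (adjusted p = 0.45), glycolysis, with 4 of 20 lower and 2 higher (adjusted p = 0.54), and bile acid genes, with 9 of 17 lower and 4 higher, 10 and 4 adjusted over the list alone (adjusted p = 0.15), did not pass as lists. Within them MLXIPL fell by 1.38 and CREB3L3 by 1.48, and TAT rose by 1.85 and PFKP by 1.69. Of 10 cholangiocyte and progenitor markers 4 rose, SOX4, CD24, KRT19 and SPP1 by 2.08, 1.59, 1.35 and 0.96, SOX9, named after its value was seen, fell by 0.37 and 5 did not pass, and neither did the list (adjusted p = 0.062).

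In all, 5607 genes changed (31.7%), 2649 higher and 2958 lower, and 1131 at least 2-fold. The number fell to 3545 without siIPO8-NC replicate 2 and to 3551 without siIPO8-miR-552-3p replicate 1. Scaled by library size alone, 36.7% of the called genes were higher, against 47.2% with the main scaling and at most 50.9% in any setting.

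The third question was whether the mimic acts alike with control siRNA and with importin8 siRNA. The IPO8 transcript was lowered by that siRNA but not absent, and protein was not measured in these libraries. Most genes moved the same way in both arms, and by less with the importin8 siRNA. Of 4855 genes called in both arms 4668 (96.1%) had the same direction, with 2262 higher in both against 766 for independent calls and 2406 lower in both against 872. Their median absolute log2 fold change was 1.02 with control siRNA and 0.56 with importin8 siRNA. Of the 11093 genes called in either arm, 84.1% had the same direction. Of these, 5486 were called with control siRNA only and 752 with importin8 siRNA only. Across all 17715 genes, which are not independent replicates, Pearson's r between the effects, which share no library, was 0.515 and Spearman's rho 0.622. AKAP12 (chromosome 6, 151239999 to 151358557) was at 16.4 ± 0.779 and 2218 ± 23.5 CPM without and with the mimic under control siRNA, and at 86.4 and 766 CPM under importin8 siRNA.

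**Figure D2:**
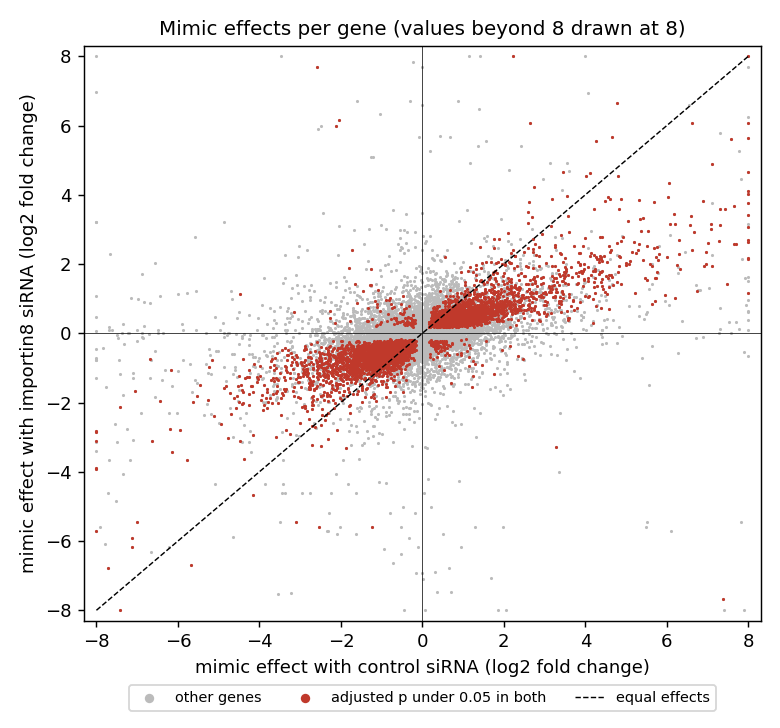
Log2 fold change of each tested gene with the mimic under control siRNA (x axis) and under importin8 siRNA (y axis); red points are the 4855 genes called in both, the dashed line marks equal effects and values beyond 8 are drawn at 8. Most red points lie in the quadrants of the same direction, at smaller values on the y axis.

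A test of the difference between the mimic effects called 5551 genes (31.3%), 2513 with a higher and 3038 with a lower value under importin8 siRNA, and 1930 of them at least 2-fold. Of the 5551 genes 5125 had a smaller absolute effect under importin8 siRNA. The share with a higher value was 51.7% with upper-quartile scaling, against 45.3%. NR1H4 differed by 1.18 (SE 0.10; adjusted p = 1.6e-05), FASN by 1.24 (adjusted p = 0.00019), SCD by 1.07 (adjusted p = 6.5e-05), ACACA by 0.88 (adjusted p = 0.00014) and NR0B2 by 0.53 (adjusted p = 0.0026), each with the smaller effect under importin8 siRNA. ABCA1 differed by -0.96 (adjusted p = 0.00029) and CYP7A1 by -1.58 (adjusted p = 0.00059). PCK1, NR1H3 and SREBF1 had differences of 0.28, -0.17 and 0.03 that did not pass.

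Of 25 cholesterol genes 22 had a higher and 1 a lower value, also adjusted over the list alone, LSS at 1.69, MVK at 1.68 and EBP at 1.61. The median was 1.05 (adjusted p = 7.3e-14, and adjusted p = 0.24 with an estimated correlation). Fatty acid and triglyceride synthesis, with 10 of 17 higher and 1 lower and 11 and 1 adjusted over the list alone, had a median of 0.54 (adjusted p = 4.2e-05, and adjusted p = 0.47 with an estimated correlation), PNPLA3 at 1.62. The lipoprotein list, with 7 of 18 higher and 2 lower and 8 and 2 adjusted over the list alone, had a median of 0.50 (adjusted p = 0.0020, and adjusted p = 0.57 with an estimated correlation), APOA5 at 2.19 and CIDEC, a lipid droplet protein, at -2.16. The hepatocyte list, with 14 of 30 higher and 4 lower and 16 and 7 adjusted over the list alone, had a median of 0.32 (adjusted p = 0.046, and adjusted p = 0.71 with an estimated correlation), HPX at 2.73 and FGA at -2.39. That call was lost without NC replicate 1, siIPO8-NC replicate 2 or either siIPO8-miR-552-3p library, at adjusted p = 0.052 to 0.13. Among lists with lower values, the stress response had 13 of 21 lower and 1 higher, 14 and 2 adjusted over the list alone, CHAC1 at -3.08 and DDIT3 at -1.79. The median was -0.51 (adjusted p = 0.00014, and adjusted p = 0.57 with an estimated correlation). The p53 targets had 9 of 20 lower and 3 higher, 10 and 3 adjusted over the list alone, PMAIP1 at -1.93 and TP53INP1 at 2.33. The median was -0.31 (adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation). Importins and exportins had 9 of 21 lower and none higher, 13 and 1 adjusted over the list alone, KPNA3 at -0.68 and KPNA4 at -0.58. The median was -0.23 (adjusted p = 0.0050, and adjusted p = 0.59 with an estimated correlation). Ribosomal proteins had 7 of 26 lower and none higher, 6 adjusted over the list alone, RPS14 at -0.56. The median was -0.33 (adjusted p = 0.00031, and adjusted p = 0.72 with an estimated correlation). These differences rest on the NC libraries as much as on the other groups.

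The fourth question was what the importin8 siRNA changes without the mimic, a comparison of siIPO8-NC with NC. The control siRNA libraries also have a table of their own. The labels do not say whether both siRNA arms were handled together. A batch difference between the arms therefore cannot be told from the siRNA here, nor in the siRNA comparison among the mimic libraries. CYP7A1 rose from 1.55 ± 0.348 to 21.8 ± 0.756 CPM and NR0B2 from 131 to 317 CPM, while NR1H4, at 74.0 and 80.9 ± 5.38 CPM, did not pass. Cell cycle genes, FXR targets, bile acid genes and importins rose as lists, and cholesterol genes fell. Each of these calls was lost with an estimated correlation, at adjusted p = 0.30 to 0.57. CTGF, CYR61 and ANKRD1, known targets of the YAP coactivator, rose strongly, CTGF from 11.8 ± 4.4 to 504 ± 42.2 CPM. SLC6A12 (chromosome 12, 190077 to 214570) and ETNPPL fell here as with the mimic, to 3.14 ± 0.0690 and 3.35 ± 0.101 CPM. The NC libraries, at -88.8 and -94.3 on the first principal component and 36.9 and 38.7 on the second, are the reference of this comparison as of the first.

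LEAP2, a liver antimicrobial peptide, had no counts in NC and was at least 97.1-fold higher at 12.9 ± 0.168 CPM; the histone gene HIST2H2BE was at 9.60 ± 0.431 CPM in NC, had no counts in siIPO8-NC and was at least 71.2-fold lower. HAL, the first enzyme of histidine breakdown, rose by 6.59, HSPA6 by 5.78, the alcohol dehydrogenase ADH4 by 5.56, TCIM by 4.95, ANKRD1 by 4.82, IGFBP1, a binding protein of insulin-like growth factors, by 4.28, TDGF1 by 4.03, SLC16A6 by 4.01, CYR61 by 3.89 and HAMP by 3.87. GLP2R went from 29.9 ± 1.35 CPM to 1 and 2 counts. SLC6A12 changed by -7.07, RANBP3L by -7.02, PTGS1 by -6.65, SLC4A3 by -6.33, ETNPPL and SLC7A10 by -5.89 each, PLAU, the urokinase gene, by -5.57, AQP6 by -5.55 and ELF5 by -5.49.

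CYP7A1 rose by 3.80 (SE 0.16; adjusted p = 1.1e-07), NR0B2 by 1.28 (adjusted p = 5.0e-07), ABCA1 by 1.12 (adjusted p = 5.2e-06), PCK1 by 1.02 (adjusted p = 0.00078), SREBF1 by 0.36 (adjusted p = 0.0059) and NR1H3 by 0.34 (adjusted p = 0.0039, a call lost with DESeq2). FASN, SCD and ACACA fell by 0.51, 0.43 and 0.38. G6PC fell by 0.59 (adjusted p = 0.033), a call lost with DESeq2 and without NC replicate 1 or either siIPO8-NC library, at -0.60 to -0.42 and adjusted p = 0.12 to 0.23. NR1H4 had a value of 0.13 (adjusted p = 0.14).

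Of 28 cell cycle genes 24 rose and none fell, also adjusted over the list alone, with CCNA2 at 1.99, CDK1 at 1.80 and RRM2 at 1.5. The median was 0.82 (adjusted p = 3.7e-10, and adjusted p = 0.30 with an estimated correlation). Of 20 FXR targets 10 rose and 1 fell, also adjusted over the list alone, SLC51A, a bile acid exporter subunit, at 2.79, FGB at 2.68 and KNG1 at 2.46. The median was 0.39 (adjusted p = 0.0029, and adjusted p = 0.47 with an estimated correlation). CYP7A1, which FXR activity lowers, is one of the members that rose. Of 17 bile acid genes 12 rose and 1 fell, also adjusted over the list alone, AKR1D1 at 1.93. The median was 0.53 (adjusted p = 0.0027, and adjusted p = 0.47 with an estimated correlation). Of 25 cholesterol genes 18 fell and 2 rose, 18 and 3 adjusted over the list alone, LSS from 222 ± 24.5 to 74.2 ± 9.91 CPM, HMGCS1 at -1.21 and STARD4 at -1.06. The median was -0.58 (adjusted p = 8.1e-06, and adjusted p = 0.30 with an estimated correlation). Of 21 importins and exportins 16 rose and 2 fell, also adjusted over the list alone, IPO8 itself among the latter, with CSE1L at 1.12, IPO5 at 0.79 and IPO11 at 0.75 (median 0.35; adjusted p = 0.00095, and adjusted p = 0.57 with an estimated correlation).

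Of 30 hepatocyte genes 18 rose and 7 fell, also adjusted over the list alone, FGA at 3.67, FGG at 2.55 and NR5A2 at -2.51. The median was 0.39 (adjusted p = 0.014, and adjusted p = 0.68 with an estimated correlation). Of 21 stress genes 13 rose and 2 fell, also adjusted over the list alone, CHAC1 at 2.04, DDIT3 at 1.22 and DNAJB9 at -1.03. The median was 0.50 (adjusted p = 0.0042, and adjusted p = 0.66 with an estimated correlation). Of 26 ribosomal protein genes 11 rose and none fell, also adjusted over the list alone, RPS14 at 0.39. The median was 0.26 (adjusted p = 0.0027, and adjusted p = 0.77 with an estimated correlation). Of 24 oxidative phosphorylation genes 8 rose and none fell, also adjusted over the list alone, CYC1 at 0.73 (median 0.15; adjusted p = 0.036, and adjusted p = 0.78 with an estimated correlation), a call lost without NC replicate 2 or siIPO8-NC replicate 1 at adjusted p = 0.12 to 0.20. Of 20 glycolysis genes 11 rose and 2 fell, 12 and 2 adjusted over the list alone, SLC2A2, the liver glucose carrier, at 2.93, HK2 at 2.12 and HK1 at -2.37. The median was 0.34 (adjusted p = 0.046, and adjusted p = 0.77 with an estimated correlation). That call was lost without NC replicate 2, siIPO8-NC replicate 1 or any of the 4 mimic libraries, at adjusted p = 0.052 to 0.085. LXR targets did not pass, with 10 of 18 higher and 3 lower (median 0.35; adjusted p = 0.056), CETP at 1.2, and neither did fatty acid and triglyceride synthesis, with 10 of 17 lower and 4 higher (median -0.38; adjusted p = 0.12), LPIN1 at -1.23 and AGPAT2 at 1.71. Gluconeogenesis, with 5 of 10 higher and 3 lower, had adjusted p = 0.57, FOXO1 at 1.71.

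In all, 8329 genes changed (47.0%), 4497 higher and 3832 lower, and 2493 at least 2-fold. Leaving out single libraries gave 6427 to 8163 genes, and upper-quartile scaling turned the majority, with 47.1% higher against 54.0%. Because the mimic and siRNA comparisons with NC share its libraries, they were also set against each other: 6422 genes were called in both and 82.6% of these went the same way. Chance values of shared controls alone gave r = 0.505 in 20 simulations and the data gave r = 0.561. The simulated r follows from sharing a control, whatever the size of the noise, so r decides nothing here. The covariance was 0.896 in the data, from fitted fold changes, and 0.083 in the simulations, from log2 CPM, which are damped near 0 counts.

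After NC was seen at one end of the first principal component, the importin8 siRNA effect was also taken among the mimic libraries, siIPO8-miR-552-3p against miR-552-3p. CYP7A1 again rose, by 2.22 (adjusted p = 5.7e-06), and so did NR0B2 by 1.81 and PCK1 by 1.30, and IPO8 fell by 1.65. NR1H4, which had not passed with control mimic, rose by 1.31. LEAP2 had no counts in miR-552-3p and was at least 95-fold higher at 13.2 ± 5.97 CPM, and HIST2H2BE was at least 86.3-fold lower, from 12.4 ± 1.89 CPM to no counts. HAL rose by 2.71, the acyl-CoA synthetases ACSM2A and ACSM2B by 2.71 and 2.64, the glutathione transferase GSTA1 by 2.69, CCL16 by 2.68, HSD17B2 by 2.51, transthyretin TTR by 2.29, AKR1D1 by 2.27 and MEP1A by 2.16. IGFN1 changed by -4.98, TFPI2 by -4.77, PDE7B by -4.44, CD79A by -4.41, TAGLN3 by -4.21, GEM by -3.99, TM4SF19 by -3.79, PMP22 by -3.31, ATP6V0D2 and MMP1 by -3.29 each and CFL2 by -3.25. In all 5934 genes changed, 3069 higher and 2865 lower (51.7% higher, and 48.0 to 54.6% over other tools, scalings, filters and left-out libraries), and of 3973 called in both siRNA comparisons 74.8% went the same way. Across all genes Pearson's r between the siRNA effects was 0.208. The cholesterol median was -0.58 with control mimic but 0.55 with the mimic. For fatty acid and triglyceride synthesis it was -0.38, which did not pass, and 0.50. Medians of cell cycle genes (0.82 and 1.04) and FXR targets (0.39 and 0.60) kept their direction.

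**Figure D3:**
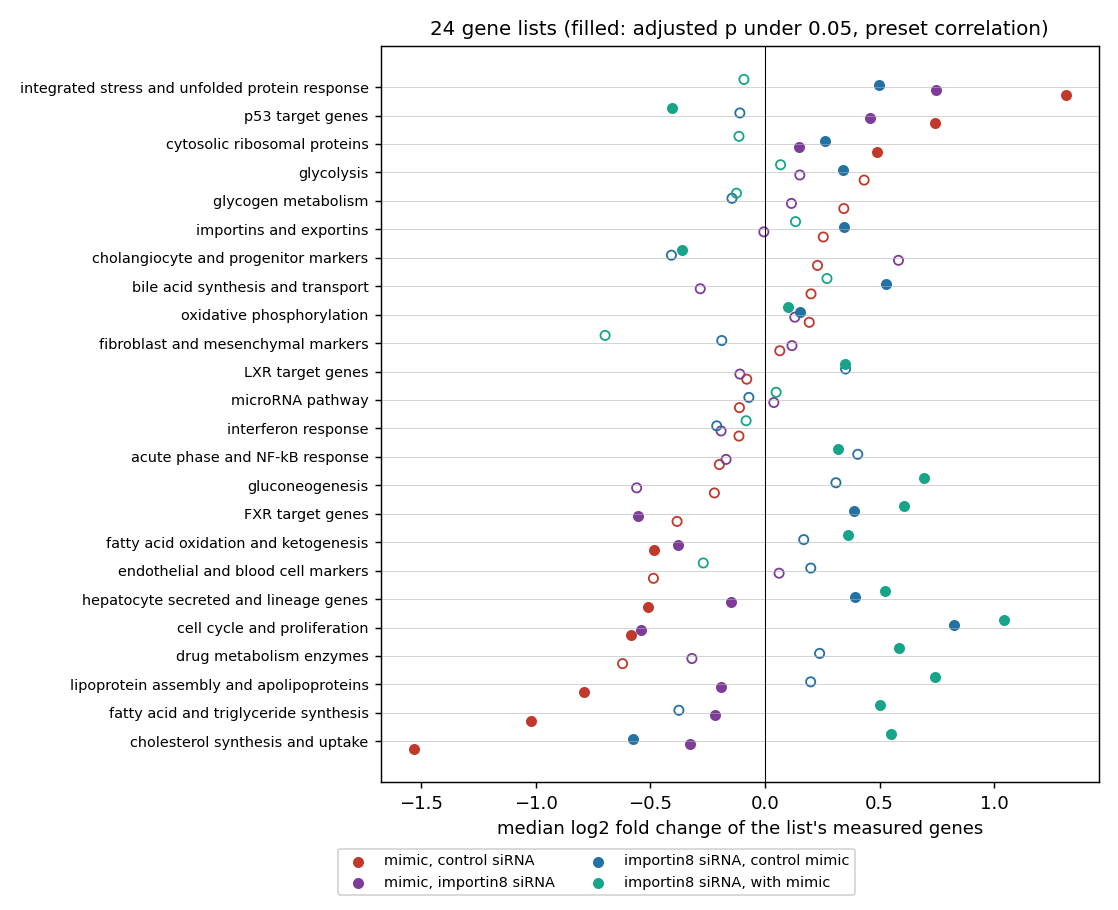
Median log2 fold change of each of 24 gene lists (x axis) in 4 comparisons, the mimic with control or importin8 siRNA and the siRNA with control mimic or mimic; filled points have an adjusted p under 0.05 with the preset correlation. The median of the cell cycle genes was -0.58 and -0.54 with the mimic and 0.82 and 1.04 with the siRNA.

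The last question was whether genes with a site for the mimic's seed fell. The 3' UTRs of 2605 of 13544 genes (19.2%) held CACCTGT, the match to positions 2 to 8 of miR-552-3p. The mean log2 fold change of these genes, with UTR length taken out, was shifted by -0.131 with the mimic and control siRNA (95% interval over genes -0.186 to -0.076) and by -0.0967 with the mimic and importin8 siRNA (-0.127 to -0.0667). Ranked among all heptamers from the lowest, these stood at 1.17% and 0.03%, where the lowest or highest 2.5% would pass. With control siRNA the pass was lost for the hexamer of positions 2 to 7 (8.47%), in the coding sequence (4.05%) and 5' UTR (9.47%), and without Alu-like UTRs and with GC content taken out (6.81%; shift -0.0722, -0.158 to 0.0139). With importin8 siRNA it was lost in the coding sequence (4.64%) and 5' UTR (62.02%). With the importin8 siRNA alone the shift was -0.0215 and stood at 31.2%. The difference between the mimic shifts was 0.0339 (-0.0083 to 0.0762), at 83.09%. GGTTAAA, the match to the other arm of the precursor, miR-552-5p, shifted by 0.115 and 0.0723 with the mimic, at 94.03% and 96.22%, and did not pass. It passed with importin8 siRNA when GC content was taken out (98.29%; shift 0.0509, 0.0125 to 0.0893) or as an octamer (98.39%; 0.0909). In the 5' UTR it stood among the lowest with the mimic and control siRNA (1.61%), and with the siRNA alone (0.6%), and among the highest for the difference between the mimic shifts (98.76%; 0.228, 0.0531 to 0.402). Of the genes that fell with the mimic 21.3% under control siRNA and 24.7% under importin8 siRNA held the site, and of those that rose 17% and 16.5%. With the siRNA alone, a comparison without the mimic, 21.2% of the fallen and 17.4% of the risen genes held it. The shares with the mimic and control siRNA were thus close to those without the mimic. Of the study's theme genes with a UTR searched, CYP7A1 alone held it. Genes are not independent replicates, so the rank among heptamers is the test, and a planted shift of -0.2 ranked first in 2 of 5 trials. That shift was larger in size than the CACCTGT shifts with the mimic. Planted shifts of the observed size were not tested.

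**Figure D4:**
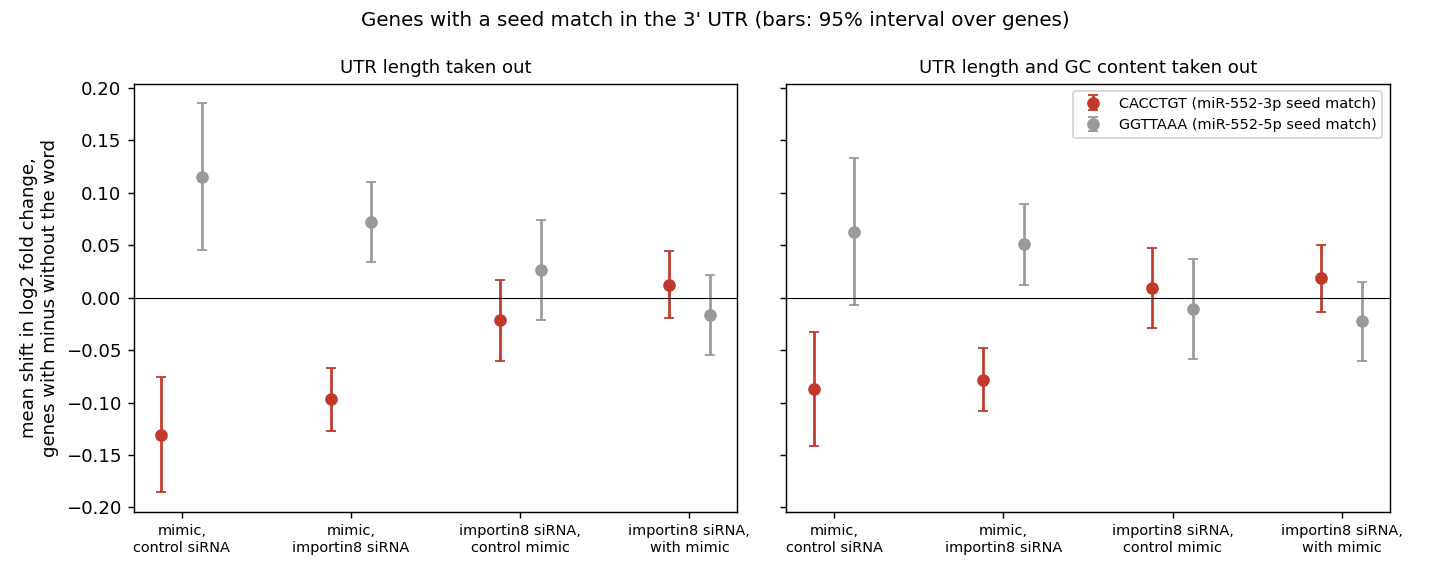
Mean shift in log2 fold change of genes with CACCTGT or GGTTAAA in the 3' UTR against genes without (y axis), in 4 comparisons, with UTR length taken out (left) or UTR length and GC content (right); bars are 95% intervals over genes. The CACCTGT shift was -0.131 and -0.0967 with the mimic and -0.0875 and -0.0783 with GC content taken out as well.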

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

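The test of chance values in shared controls and that of genes called with importin8 siRNA were chosen only after the results were seen, while the other tests here were written down first. The mimic effects were tested for a difference between the siRNA arms, and 5551 genes passed that test (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). The genes with the largest differences in log2 were GLP2R at 9.10, SLC6A12 at 6.96, PTGS1 at 6.22, ETNPPL at 6.17, AQP6 at 6.11 and RANBP3L at 5.96, which fell with the mimic from their levels in NC and had a mean of 4.06 CPM (ETNPPL) or less in every group but NC. On the other side were HSPA6 at -7.19, ATP6V0D2 at -6.47, IGFN1 at -6.14, CA12 at -6.07, ESAM at -6.01 and ANKRD1 at -5.52, which rose most in miR-552-3p. Fitted values of genes near 0 counts depend on the prior count and are no bound. AQP6 lost its call without siIPO8-miR-552-3p replicate 2 (5.59; adjusted p = 0.085), and ESAM without either NC library (adjusted p = 0.052 to 0.065). Of the theme genes, the same test found NR1H4 at 1.18, NR0B2 at 0.53, FASN at 1.24, SCD at 1.07, ACACA at 0.88, G6PC at 1.54 (lost with DESeq2), CYP7A1 at -1.58 and ABCA1 at -0.96. The list medians of this difference were 1.05 for cholesterol, 0.54 for fatty acid and triglyceride synthesis, 0.50 for lipoproteins, 0.32 for hepatocyte genes, -0.31 for p53 targets, -0.51 for stress responses, -0.23 for importins and exportins and -0.33 for ribosomal proteins. The hepatocyte list lost its call without NC replicate 1, siIPO8-NC replicate 2 or either siIPO8-miR-552-3p library (adjusted p = 0.052 to 0.13), and all 8 lists lost theirs with an estimated correlation.

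The mimic and the siRNA effects against NC went the same way in 82.6% of the 6422 genes called in both, and NC lay at one end of the first principal component, but beside miR-552-3p on the second (36.9 and 38.7 against 44.8 and 45.1) and nearer to siIPO8-NC (0.906) than miR-552-3p was (1.04, root mean square of log2 differences). The latter pair differs in both treatments. Among pairs that differ in 1 treatment, those with NC lay farther apart. For the siRNA the distance was 0.906 with NC and 0.705 between the mimic groups. For the mimic it was 1.26 with NC and 0.669 between the importin8 siRNA groups. Chance values of single libraries in the shared controls are argued against as the whole cause. The covariance of both effects was 10.8 times the one simulated for unchanged groups. The simulated one came from log2 CPM, where a prior count damps values near 0 counts, the observed one from fitted fold changes. The ratio thus mixes scales, and its size is approximate. That simulation used the spread between libraries of a group, which may be technical. A chance deviation common to both NC libraries is not in that spread, so the test cannot decide on it. A different cell density in the NC cultures stays open as a candidate explanation: of 16 measured YAP targets not looked at before, 11 rose, 1 fell and 4 did not pass with the mimic, and 9 rose, 3 fell and 4 did not pass with the siRNA, with medians of 0.69 and 0.41, the lower of which decided the test at 0.411, while AMOTL2 went against it at -1.27 in both. A different osmotic state, which would lower targets of NFAT5 such as SLC6A12 in every group but NC, cannot be told apart, because the 6 targets not looked at before went both ways from -2.27 to 1.37 with the mimic (median -0.0387), while with the siRNA 3 fell and 1 rose (median -0.87; -2.56 to 0.38); the bound written for exclusion was met with the mimic, but a median over members that move both ways was judged to decide nothing. A shared response of the cells to either active RNA is named by the design and stays open as untested, and no other control libraries are held to tell it from a state of the NC cultures.

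Mimic effects were smaller under importin8 siRNA in 5125 of the 5551 genes called for the difference, with a slope of 0.328 over the 10341 genes called with control siRNA, a choice that favours large effects there. The NC libraries alone are argued against as the whole cause: of 682 genes called with the mimic and importin8 siRNA, a choice that favours large effects in that arm, whose siIPO8-NC and NC levels differed by less than 0.1 in log2 with no call, 74.3% had the larger mimic effect under control siRNA (72.0 to 75.9% without any 1 library), where no more than 50% would be needed and counts simulated with the same effect in both arms gave 32.5 to 37.7%. Slopes weigh less: over 1154 such genes called with control siRNA instead, that of the effect under importin8 siRNA on the other was 0.505, against 0.776 to 0.977 in those simulations, and over the 682 the reverse slope was 1.11, against 0.813 to 0.891, but 0.889 without siIPO8-miR-552-3p replicate 2. A weaker direct action of the mimic cannot be told apart, since the shift of genes with its seed match was 0.740 times as large under importin8 siRNA, or 0.895 times with GC content taken out, and the interval of the difference (-0.0083 to 0.0762) held 0, which left it undecided although the ratio met the bound written beforehand. A need of the mimic's action for importin8, which the design names, stays open as untested.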

How the results depend on the processing

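Library size alone, the siRNA effect among mimic libraries, and the GC and Alu versions of the word test were chosen only after the data were seen. Of 594 single-gene results 513 kept direction and side of the threshold in every setting run, as did 35 of 120 list results, and none reversed. No called gene was called the other way in any setting, and the IPO8 effects kept their calls in all. A minimum of 2-fold left 4432 genes with the mimic and control siRNA, 1131 with the mimic and importin8 siRNA, 2493 with the siRNA and control mimic, 1930 for the difference and 1367 with the siRNA and mimic, by its construction. With single libraries left out the genes called with the mimic and importin8 siRNA numbered 3545 to 6087, lowest without siIPO8-NC replicate 2 and at 3551 without siIPO8-miR-552-3p replicate 1; an arm then has 1 library, assumed to vary like the other groups. DESeq2 gave 8563, 4010, 6587, 4058 and 4358 genes in the order above. The replicate number as a block gave 10424, 5847, 8496, 5786 and 6121. Differences between replicates correlated little between groups over all genes (-0.00335 to 0.0867). On the fourth principal component, with 5.15% of the variance, replicate 1 lay below 0 and replicate 2 above 0 in every group. An effect shared by replicate number thus cannot be excluded, and the labels give no source for it. The correlation of the mimic effects was 0.700 over genes of at least 40 counts, 0.661 from fits of 4 libraries and 0.622 by ranks. With single libraries left out it was 0.357 to 0.441, below 0.515 whichever library was dropped. The count filter kept more genes in those fits, 18393 to 18585 against 17715. Whether the added genes lowered the correlation was not tested. With an estimated correlation 0 lists passed in each of the 5 comparisons, and with fry, which does not compare a list with other genes, 18 passed with the mimic and control siRNA, 6 up and 12 down. The seed shift with control siRNA was outside the lowest 2.5% of words with the hexamer at -0.0914 (8.47%), in the coding sequence at -0.0928 (4.05%), in the 5' UTR at -0.140 (9.47%) and without Alu-like UTRs, GC content taken out, at -0.0722 (6.81%). With importin8 siRNA it was -0.0369 (4.64%) in the coding sequence and reversed to 0.0095 (62.02%) in the 5' UTR. Between the mimic groups the hexamer gave 0.0417 (99.95%), inside the highest 2.5%; the cause was not tested. Other pseudocounts and quantile normalization, meant for normalized values, were not run, since the tables hold counts. At this depth genes such as CYP2E1 and FBP1 could not be tested.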

Other observations

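The siRNA comparison among mimic libraries, its lists, the words CCAATTA and CAATTAA, the GC-corrected words and the tests of Alu repeats were chosen only after the data were seen. With siIPO8-miR-552-3p against miR-552-3p, which contrasts no NC library but was fitted with all 8, several lists of liver and lipid genes passed as rising. The list of bile acid synthesis and transport did not pass (median 0.27). Of 30 hepatocyte genes 24 rose and 1 fell, AHSG at 1.68, CEBPA at 1.28 and FGA at 1.28 (median 0.52; adjusted p = 5.1e-10, and adjusted p = 0.17 with an estimated correlation). Of 18 lipoprotein genes 12 rose and none fell, APOM at 1.86, APOC3 at 1.75 and APOA5 at 1.49 (median 0.74; adjusted p = 1.4e-06, and adjusted p = 0.18 with an estimated correlation). Of 25 cholesterol genes 16 rose, 17 adjusted over the list alone, and none fell, ACAT2 at 1.33 (median 0.55; adjusted p = 4.0e-07, and adjusted p = 0.13 with an estimated correlation). Of 20 FXR targets 11 rose and 4 fell, 11 and 5 adjusted over the list alone, SLC51A at 2.05 and UGT2B4 at 2.04 (median 0.60; adjusted p = 0.0026, and adjusted p = 0.18 with an estimated correlation), and of 18 LXR targets 8 rose and 2 fell, CETP at 1.22 and MLXIPL at 1.06 (median 0.35; adjusted p = 0.0032, and adjusted p = 0.17 with an estimated correlation). Of 10 gluconeogenesis genes 8 rose and 1 fell, CREB3L3 at 1.10 and TAT at 1.07 (median 0.69; adjusted p = 0.0034, and adjusted p = 0.22 with an estimated correlation). Fatty acid and triglyceride synthesis (13 of 17 higher and 2 lower, 13 and 3 adjusted over the list alone; median 0.50; adjusted p = 0.00084, and adjusted p = 0.21 with an estimated correlation), fatty acid oxidation (11 of 21 higher and 1 lower; median 0.36; adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation) and drug metabolism (6 of 18 higher and 1 lower, 8 and 1 adjusted over the list alone; median 0.59; adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation) passed too.

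Of 28 cell cycle genes 23 rose in that comparison, 24 adjusted over the list alone, and none fell, CCNA2 at 1.91, E2F1 at 1.80 and CDK1 at 1.45 (median 1.04; adjusted p = 2.8e-15, and adjusted p = 0.13 with an estimated correlation). Of 20 p53 targets 13 fell, 14 adjusted over the list alone, and none rose, CDKN1A, the cell cycle inhibitor p21, from 348 ± 26 to 147 ± 3.85 CPM, RRM2B at -1.35 and FAS at -1.05 (median -0.41; adjusted p = 5.9e-06, and adjusted p = 0.17 with an estimated correlation). Of 10 cholangiocyte and progenitor markers 5 fell, 6 adjusted over the list alone, and none rose, KRT19 from 662 ± 20.5 to 172 ± 2.50 CPM and SOX4 from 163 ± 9.98 to 66.0 ± 4.17 CPM (median -0.36; adjusted p = 0.00068, and adjusted p = 0.17 with an estimated correlation). Acute phase genes passed as a rising list, 10 of 19 higher and 2 lower, 10 and 3 adjusted over the list alone, with a median of 0.32 but a mean of -0.12, LCN2 at -3.23 (adjusted p = 0.026, and adjusted p = 0.57 with an estimated correlation). Oxidative phosphorylation genes passed with 8 of 24 higher and 1 lower, CYC1 at 0.81 (median 0.10; adjusted p = 0.022, and adjusted p = 0.58 with an estimated correlation), a call lost without miR-552-3p replicate 2 or siIPO8-miR-552-3p replicate 1 at adjusted p = 0.058 to 0.15. LEAP2 and HIST2H2BE were the 2 genes of at least 100 counts with no counts in one siRNA arm and counts in every library of the other. By the same rule 0 genes did so between the mimic arms. Whether the siRNA or another difference between its arms set these counts cannot be told apart. LEAP2 had 291, 285, 363 and 190 counts in the importin8 siRNA libraries, and HIST2H2BE 220, 212, 241 and 291 in the control siRNA libraries.

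Genes with the miR-552-3p seed match in the 3' UTR lay lower in both mimic comparisons. GC content of the UTR, which correlated with the effects across genes at rho = -0.155 and -0.124, is argued against as the whole cause, since with it taken out the match stood in the lowest 0.11% of heptamers with control siRNA and the lowest 0.01% with importin8 siRNA, with shifts of -0.0875 (-0.142 to -0.0331) and -0.0783 (-0.108 to -0.0484); the bound of 0.1% written beforehand was narrowly missed with control siRNA, and the reading rests on ranks under 1% and intervals without 0, set after the values were seen. Alu-like stretches, present in 59.1% of UTRs with the match and 20.1% of the others, are argued against with importin8 siRNA, where the match stayed in the lowest 0.02% among 9804 genes without one (-0.0833; -0.129 to -0.0375). With control siRNA they cannot be told apart, because the match stood in the lowest 6.81% there with a shift of -0.0722 whose interval, -0.158 to 0.0139, held 0. Direct action of the mimic through its seed may account for the shift and stays open, as the match ranked 2nd with importin8 siRNA and 18th with control siRNA but stood at 72.81% with the siRNA alone.

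As a hypothesis, a strand of the importin8 siRNA could act on other transcripts through its own seed. Among the mimic libraries, genes with CCAATTA or CAATTAA in the 3' UTR held the 2 lowest standings of all heptamers with the siRNA (shifts -0.158 and -0.120, GC content taken out). In the siRNA comparison with control mimic, which shares no library with it, these words ranked 2nd and 1st with GC content taken out (-0.123 and -0.117), so the lower standing was 2 for the seed of an importin8 siRNA strand, but they stood at 7.5% and 7.09% without that correction. The IPO8 transcript holds CCAATTAA in exon 4 of 25, chromosome 12 from 30681807 to 30681814, which a transcript of 5325 bases can hold by chance. The siRNA sequence is not given in the labels used here, so this stays open.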
